A study of Mus musculus with 8 samples.

How the data were processed

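The 8 libraries were made from total RNA of satellite-cell-derived myoblasts of B6/129 mice. Per the labels' protocols, sorted reporter-positive cells were grown in medium with 20% serum and 2.5 µM 4-hydroxytamoxifen and differentiated for 24 h. Libraries were assigned to groups from their titles. Per the submitters' processing notes, the tools were Bowtie2 2.2.4, TopHat2 2.0.12, Cufflinks 2.2.1, HTSeq 0.6.1, bedtools 2.16.2, Cuffdiff and edgeR, and the build was mm9. The notes give no role or order, and the reference annotation is not given in the sources used here. Per the file headers, the authors deposited 3 gene tables in the tracking layout of Cufflinks and Cuffdiff, each with FPKM (fragments scaled by transcript length and by mapped fragments), a lower and an upper confidence bound and a status for 2 columns. The confidence level and the scaling between libraries are not stated. The female and male KO tables hold 1 library per column, and the KI table holds 1 pooled column for the 2 libraries of each group, so the test across replicates planned for KI could not be run and that comparison is described like the others.

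The tables held 23115, 28603 and 28748 loci (female, male, KI). Of these 0, 5680 and 5971 had no gene symbol and were left out, as were 6, 63 and 16 loci whose status was not OK in both columns. Symbols merged on 1 locus (262, 562 and 778 loci) were kept as merged. A gene was kept with at least 1 FPKM in 1 column. The loci are mm9; for 212 of 213 microRNA loci whose width lay within 5 bases of the RefSeq length, width and length were equal only with starts counted from 0, so starts are printed 1 higher. The reference used here was another build (GRCm38), so it served only for symbols, transcript lengths and GC content. FPKM was estimated without a stated strand, so values of overlapping or antisense genes and of close paralogues are uncertain. An exact 0 in such a table can be a failed estimate, so a gene at 0 is called listed at 0 and no fold is given against it.

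For each gene the ratio log2((FPKM + 1)/(FPKM + 1)), mutant over control, was formed within a table; the pseudocount of 1 FPKM understates the change of low genes. With 1 column per group there is no test across samples: the summary is the number of genes at least 2-fold higher or lower, and the deposited intervals are the only error. FPKM keeps no total count, so read depth is unknown and the relative worth of 1 read was read from the most frequent ratio of low values. Each of 29 gene lists was summarised by its median, its members past 2-fold, and the range of 95% of the medians of 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. The KO effect over both sexes was tested with limma (version 3.58.1, R 4.3.3), with a mean-variance trend, on the female and male ratios against 0, so that the difference between the sexes is the replicate error (1 residual degree of freedom), with Benjamini-Hochberg adjustment at 0.05 over all genes and over each list alone. The tables were estimated separately, so no level was tested across them. Whether the single libraries of a group stand for separate animals is not stated. Ratios were correlated across genes and 2-fold lists were compared with n1 × n2 / N.

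The comparisons, lists, settings and naming rule were fixed before the data were examined. Named are Kdm6a, Kdm6b, Uty, Xist and Y-linked genes; the 10 highest and 10 lowest genes with a symbol and at least 5 FPKM in 1 column; over both sexes the 10 highest and lowest by the smaller ratio; of each list the highest and lowest members; and Pax7, Myf5, Myod1, Myog, Mef2c, Myh3, Ckm, Acta1 and Tmem8c. Because small RNA genes filled most of the first ranking, a ranking of 15 genes per direction without them was added after the values were seen, and genes taken from it, other members of a list, and genes in the closing part were chosen after their values were seen. The lists covered the UTX and MLL3/4 complexes, PRC2, satellite cells and myoblasts, differentiation regulators, sarcomere and contraction, fusion, Notch, Wnt targets, cell cycle, cell cycle exit, p53 targets, Hox genes, matrix, interferon, chemokines and inflammation, immediate early and stress genes, the unfolded protein response, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, X- and Y-linked genes, and markers of fibro-adipogenic, endothelial, immune, pericyte and smooth muscle, adipocyte, Schwann and glial, and erythroid cells.

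Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, median-centred ratios, TPM over all loci, non-overlapping deposited intervals, every status, and, for the joint fit, no trend and the KI ratio as an additional value. TPM over loci with a symbol, loci without a symbol and leaving out small RNA genes were added after seeing the data, as was the correlation of male KO with KI ratios. Tables were handled with python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The steps were tested on simulated data. In the ratio step, 100 of 100 simulated 8-fold changes were recovered in each table, and 99, 100 and 99 of 100 smaller ones, with 0 false calls. The simulated noise was set well below the SD of the measured ratios (0.61, 0.84 and 0.60). Only genes with at least 5 FPKM in the control column were used. These counts thus check the computation and do not give the error rate of the 2-fold rule in these data. Of 100 unchanged random lists 2, 10 and 3 lay outside the 95% range. In the joint fit, 30 of 100 simulated 2-fold and 100 of 100 8-fold changes were called among 10482 genes, with 16 false calls. Its simulated noise depended on expression level only, so differences in spread from gene to gene were left out.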

Results

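RNA was sequenced from primary mouse myoblasts, the dividing muscle precursors that grow out of satellite cells (muscle stem cells), after 24 h of differentiation. Their mice carried a tamoxifen-dependent Cre recombinase driven by Pax7 and a Cre-dependent red fluorescent reporter at Rosa26. The cells were sorted for the reporter. The series asked what UTX contributes to gene expression in these cells. UTX is the X-linked histone H3 lysine 27 demethylase encoded by Kdm6a. The 8 libraries formed 6 groups: 1 library each of female wild type (WT), female UTX knockout (KO), male WT and male KO, and 2 libraries each of female KI and female Ctrl-KI. The labels do not say what allele KI carried. Expression was given as FPKM in 3 tables, 1 per comparison. The KI table held 1 pooled value per group, so no group had replicate values and no single comparison has a p-value or a replicate check.

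After genes under 1 FPKM in both columns were left out, 12344 genes remained in the female table, 11440 in the male table and 11084 in the KI table. Read depth was not given. Values under 0.3 FPKM move in steps of single reads, and their most frequent mutant-to-control ratio was 0.662 in the female table, 0.983 in the male table and 0.841 in the KI table. By this measure 1 read was worth about the same in both male libraries and less in the mutant columns of the other tables. The deposited confidence interval spanned a median of 119% of the FPKM in the female control column, 171% in the male one and 40.0% in the KI one. The median log2 ratio over all genes was -0.08, -0.02 and -0.04 in the female, male and KI tables. Paired values below give the control column first and the mutant column second.

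Kdm6a itself (mm9 chromosome X, 17739793 to 17856484) was 20.8 FPKM in female WT and 16.9 in female KO cells, with deposited intervals of 9.71 to 31.9 and 7.95 to 25.8. In males it was 7.87 FPKM in WT and 2.08 in KO cells (intervals 1.57 to 14.2 and 0.0854 to 4.07), and in the KI table it was 12.8 and 13.2 FPKM. These are values over the whole gene and the floxed part is not given, so they check the deletion only weakly, above all in females. Kdm6b, another H3 lysine 27 demethylase, was 48.6 and 56.8 FPKM in female WT and KO cells. In the other tables it is merged with Tmem88, at 29.8 and 19.4 FPKM in males and 30.2 and 34.6 in the KI table. Uty, the Y-linked paralogue of Kdm6a, was 8.43 and 5.85 FPKM in males and listed at 0 in both female libraries. The Y-linked genes Ddx3y (25.6 and 17.0 FPKM), Eif2s3y (35.1 and 24.1) and Kdm5d (5.38 and 4.30) were read in male WT and KO cells and stayed under 0.1 FPKM in the female and KI columns. Xist, the X-inactivation RNA, was 219 and 149 FPKM in female WT and KO cells, 34.8 and 38.8 in Ctrl-KI and KI cells, and 0.0387 and 0.0441 in males. These values match the sex labels.

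**Figure D1:**
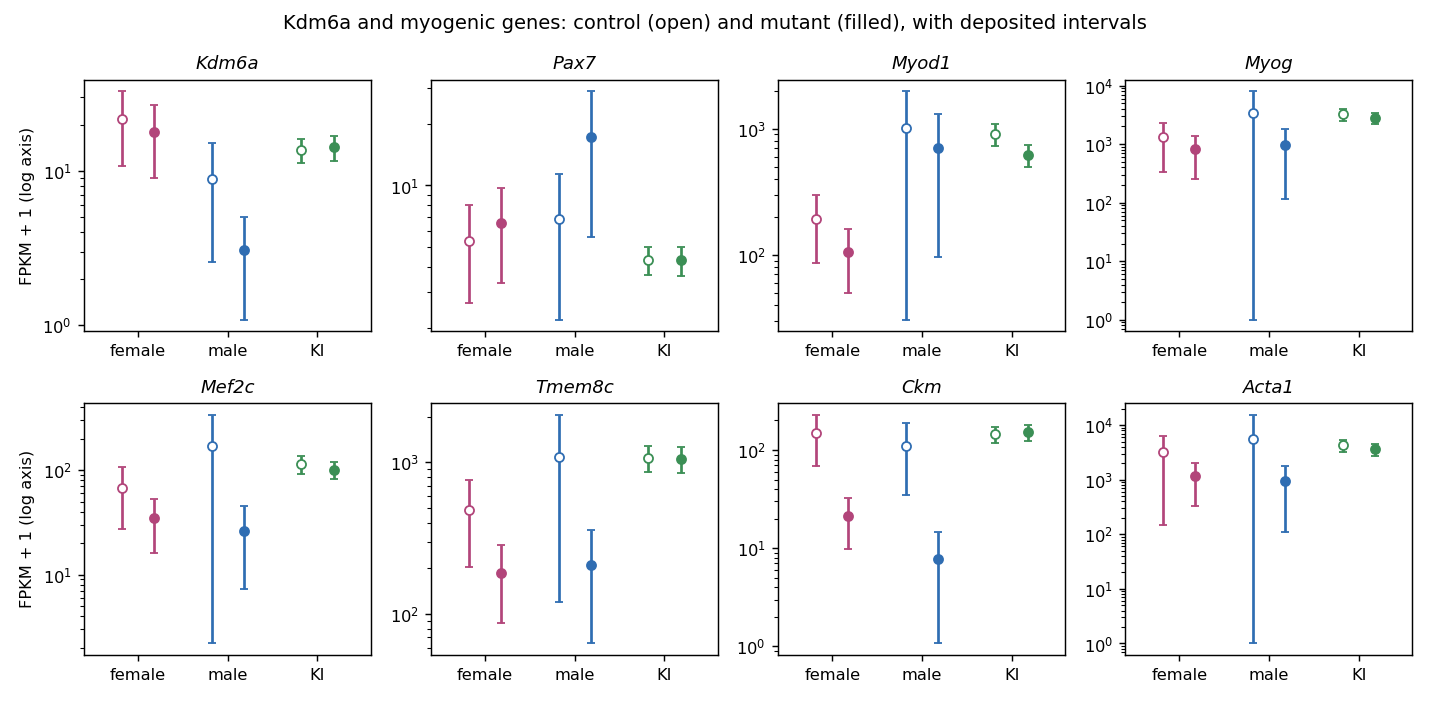
FPKM + 1 on a log axis of Kdm6a and 7 myogenic genes in the control (open) and mutant (filled) column of the female, male and KI tables, with bars for the deposited confidence intervals. Ckm was 147 and 20.2 FPKM in female WT and KO cells and 110.0 and 6.82 in male WT and KO cells, against 143 and 152 in Ctrl-KI and KI cells.

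In the female KO myoblasts, the contractile programme was expressed at a lower level than in WT. All 55 measured sarcomere and contraction genes lay below the WT value and 41 of them were at least 2-fold lower. Their median log2 ratio was -1.26, where 95% of expression-matched random lists lay within -0.35 to -0.02. The deposited intervals of the 2 columns did not overlap for 6 of the 55. Ckm, the muscle creatine kinase, was 147 and 20.2 FPKM, log2 ratio -2.81. Tnnc2, fast skeletal troponin C, was 459.9 and 77.1 FPKM, log2 ratio -2.56, and Atp2a1, the calcium pump of the fast-fibre sarcoplasmic reticulum, 677 and 163 FPKM, log2 ratio -2.05. Skeletal actin Acta1 was 3278 FPKM in WT and 1180.1 in KO cells (log2 ratio -1.47), and Myh3, the embryonic myosin heavy chain, 786 and 483 (log2 ratio -0.70). The regulators of muscle differentiation were lower as well, with a median of -0.83 and 4 of 14 at least 2-fold lower, though intervals were apart for 0 of 14. Smyd1, a muscle methyltransferase, was 42.7 and 15.9 FPKM, Smarcd3, a muscle subunit of the SWI/SNF complex, 77.0 and 34.4. Mef2c was 66.4 and 33.5 (log2 ratio -0.96) and Myog, which drives the onset of differentiation, 1305 and 817 (log2 ratio -0.68).

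The genes that mark the earlier myoblast differed less uniformly. Pax7, the satellite cell transcription factor, was 4.33 and 5.54 FPKM in female WT and KO cells (log2 ratio 0.30), Myf5 12.5 and 7.69 (-0.63) and Myod1 189.9 and 104 (-0.87). The satellite cell and myoblast list of 21 genes had a median of -0.04, within its random range of -0.39 to 0.12. Among fusion genes, Tmem8c, the fusion protein also called myomaker, was 484 and 185 FPKM (log2 ratio -1.38) and Stac3 95.2 and 33.5 (log2 ratio -1.48), whereas the guanine exchange factors were higher, Dock5 at 2.21 and 8.44 FPKM and Dock1 at 3.32 and 8.24. Of 19 members 2 were at least 2-fold higher and 5 at least 2-fold lower. Cell cycle genes were higher, with intervals apart for 2 of 39, a median of 0.57 and 10 of 39 at least 2-fold higher. Among them were the proliferation marker Mki67 (2.65 and 13.3 FPKM, log2 ratio 1.97) and the mitotic kinesin Kif11 (3.96 and 15.1 FPKM, log2 ratio 1.70). The cell cycle exit list had a median of -0.21, within -0.45 to 0.17, and its lowest members were the inhibitor Cdkn1c (55.02 and 26.9 FPKM) and Ccnd3 (85.3 and 43.0).

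Mitochondrial respiratory chain genes lay below WT in the female KO library in all 36 cases, with a median of -0.92 and 13 at least 2-fold lower, though intervals were apart for 0 of 36. Cox7a1 and Cox6a2, both muscle isoforms of cytochrome c oxidase subunits, were the lowest, at 64.7 and 17.2 FPKM for Cox7a1 and 135 and 46.5 for Cox6a2. Matrix, inflammatory and interferon-induced genes were higher. Of 39 extracellular matrix genes 18 were at least 2-fold higher and 1, Timp2, 2-fold lower (median 0.80, intervals apart for 1 of 39). The proteoglycan decorin, Dcn, was 15.9 and 69.4 FPKM and laminin Lama4 10.9 and 35.1. The female WT column already held Col1a1 at 127 FPKM, against 1.08 in male WT and 0.515 in Ctrl-KI cells, levels that were estimated separately and not tested. Of 17 chemokine and inflammation genes 7 were at least 2-fold higher (median 0.93), led by cyclooxygenase-2, Ptgs2 (13.7 and 95.9 FPKM, log2 ratio 2.72), and Ptx3 (7.08 and 28.6 FPKM, log2 ratio 1.87). The interferon list had a median of 0.68 with 7 of 31 at least 2-fold higher, Gbp3 (4.20 and 13.8 FPKM) and Rsad2 (3.53 and 10.7) among them. Markers of fibro-adipogenic cells, the resident connective tissue cells of muscle, were higher beside the matrix genes (median 0.98, 4 of 11 at least 2-fold), with Pdgfra at 2.46 and 13.7 FPKM. This list shares 5 of its 15 genes with the matrix list. Of the 3 immune genes kept, Csf1r was 2-fold higher (0.477 and 2.58 FPKM), and 0 of 9 endothelial genes reached 2-fold.

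Over all genes, 554 were at least 2-fold higher and 543 at least 2-fold lower in female KO than in WT cells. The intervals of the 2 columns did not overlap for 81 of the higher and 29 of the lower genes. By the rule fixed beforehand, 9 of the 10 highest and 6 of the 10 lowest genes were small RNA genes. Nearly all of these were listed at 0 in 1 column with an interval reaching 0 in the other, such as Mir3960 (0 and 2095 FPKM, interval 0 to 9262) and Mir133a-2 (97.1 and 0 FPKM). Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus (mm9 chromosome 6, 112996321 to 113027238), was the highest of the remaining genes, 3.01 and 62.7 FPKM, log2 ratio 3.99. A ranking without small RNA genes, added after the values were seen, next gave 3 matrix metalloproteinases: Mmp3 (1.74 and 27.5 FPKM, log2 ratio 3.38), Mmp13 (1.999 and 26.9 FPKM, log2 ratio 3.22) and Mmp10 (2.56 and 28.4 FPKM, log2 ratio 3.05). The interferon-induced GTPase Gbp1 was listed at 0 in WT and at 7.01 FPKM in KO cells, the protease inhibitor A2m was 3.83 and 25.5 FPKM, and the cystine transporter Slc7a11 11.96 and 70.0. At the low end stood, besides Ckm and Tnnc2, Mfap4 (12.8 and 1.38 FPKM, log2 ratio -2.54), Dhrs7c (43.1 and 7.08 FPKM, log2 ratio -2.45), the muscle integrin-binding protein Itgb1bp2 (227 and 41.3 FPKM, log2 ratio -2.43), Apobec2 (50.9 and 10.2 FPKM, log2 ratio -2.21) and the insulin-regulated glucose transporter Slc2a4 (20.2 and 3.74 FPKM, log2 ratio -2.16). The share of higher genes among these 2-fold calls, 50.5%, depended on the settings. It was 63.2% with median-centred ratios and 73.7% with values rescaled to TPM, which moved the median ratio from -0.08 to 0.10 and also let 13594 genes past the filter.

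In male myoblasts the same comparison again gave lower contractile gene expression in the KO library. Deposited intervals were apart for 7 of 47 sarcomere and contraction genes and for 0 of 14 differentiation regulators. Of the 47 sarcomere and contraction genes 40 were at least 2-fold lower, with a median of -2.25 (random range -0.29 to 0.01). The exception past 2-fold was 1 gene, Mylk2, which was 2-fold higher at 1.18 and 4.34 FPKM. Ckm was 110.0 and 6.82 FPKM, log2 ratio -3.83, Tnnc2 431 and 38.8 FPKM, log2 ratio -3.44, and Acta1 5658 and 957 FPKM, log2 ratio -2.56. Myh3 is merged with Myh4 in this table and was not estimated in WT. Of 14 differentiation regulators 11 were at least 2-fold lower (median -1.48), including Mef2c (168 and 25.4 FPKM, log2 ratio -2.68), Akap6 (43.1 and 10.7 FPKM, log2 ratio -1.92), Myog (3424 and 961 FPKM, log2 ratio -1.83) and Klf5 (116 and 32.1 FPKM, log2 ratio -1.82). Tmem8c was 1086 and 209.9 FPKM (log2 ratio -2.37) and Gm7325, the fusion peptide also called myomixer, 352 and 54.0 (log2 ratio -2.68). In the whole fusion list 4 of 16 genes were at least 2-fold lower and 2 at least 2-fold higher.

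Pax7 was higher in the male KO library, at 5.82 and 16.3 FPKM (log2 ratio 1.34), while Myf5 was 5.38 and 3.17 (-0.61) and Myod1 1005 and 701 (-0.52). The satellite cell and myoblast list split. In it 7 of 21 genes were 2-fold higher, led by caveolin-1, Cav1 (0.775 and 32.9 FPKM), and Vcam1 (5.14 and 28.5). Another 2 were 2-fold lower, Ncam1 (326 and 83.5) and Dag1 (261 and 110.5). Cell cycle genes were higher throughout, with 35 of 39 at least 2-fold higher, a median of 1.76 and intervals apart for 3 of 39. Top2a was 2.62 and 18.1 FPKM, the survivin gene Birc5 2.73 and 17.7 and cyclin B1, Ccnb1, 2.81 and 17.5. The gene below WT was E2f8, at 12.6 and 7.20. Cyclin D1, Ccnd1, in the list of Wnt targets, was 43.3 and 409.7 FPKM, log2 ratio 3.21. In that list 3 of 7 genes were 2-fold higher and 1, Wnt9a, 2-fold lower (median 0.97). Among cell cycle exit genes Cdkn1c was 228 and 49.9 FPKM and Rb1 80.1 and 27.8 in WT and KO cells, with 3 of 13 at least 2-fold lower and 1 higher (median -0.04).

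Matrix genes were higher in 21 of 32 cases by at least 2-fold (median 1.41, intervals apart for 7 of 32), and Loxl1 was 2-fold lower. Fibulin-2, Fbln2, was 6.36 and 128 FPKM, log2 ratio 4.13, and fibronectin, Fn1, 27.0 and 327 FPKM, log2 ratio 3.55. Col1a1, the type I collagen gene, was 1.08 and 2.35 FPKM. Markers of other cell types were higher beside them. At least 2-fold higher were 5 of 8 fibro-adipogenic genes (median 1.53) and 4 of 5 endothelial genes (median 2.73), and 1 of 2 immune genes, Lyz2 (0.681 and 7.94 FPKM). The endothelial signal came from endomucin, Emcn (0.0268 and 40.6 FPKM), VE-cadherin, Cdh5 (0.0388 and 12.3), Eng (1.17 and 13.3) and Pecam1 (0.0510 and 3.20). Some endothelial genes were under 1 FPKM in both libraries. Kdr was 0.0149 and 0.122 FPKM, Flt1 0.0139 and 0.244, Tek 0.0365 and 0.380 and Tie1 0 and 0.0404. A gene under 1 FPKM in WT was kept only if the KO column reached 1 FPKM, so the filter fixes the direction of its ratio. Chemokine and inflammation genes were 2-fold higher in 5 of 8 cases (median 1.43), led by Cxcl12 (6.75 and 112 FPKM) and Csf1 (21.3 and 184). The respiratory chain list had a median of -0.31, just within its random range of -0.32 to 0.02, with Cox6a2 (166 and 8.83 FPKM, log2 ratio -4.09) and Cox7a1 (7.86 and 2.65 FPKM, log2 ratio -1.28) at least 2-fold lower.

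Among male libraries, 1132 genes were at least 2-fold higher and 740 at least 2-fold lower, with intervals apart for 69 and 30 of them. Small RNA genes took 9 of the 10 places at each end, and the remaining gene of the 10 lowest was Fgf21, the muscle- and liver-secreted growth factor (mm9 chromosome 7, 52869260 to 52870860), 465 and 7.18 FPKM, log2 ratio -5.83. In females it was 128 and 62.8 FPKM. The highest remaining gene was Emcn (log2 ratio 5.34). Further high genes in the added ranking without small RNA genes included Gt(ROSA)26Sor (1.92 and 56.9 FPKM, log2 ratio 4.31), Cav1 (4.25 on the log2 scale), Tm4sf1 (5.33 and 118 FPKM, log2 ratio 4.23), the surface protein Thy1 (0.241 and 22.1 FPKM, log2 ratio 4.22), Cyp1b1 (0.378 and 23.3 FPKM, log2 ratio 4.14) and the basement membrane protein Nid1 (2.87 and 67.1 FPKM, log2 ratio 4.14). Downward it continued with Cox6a2, Ckm, the adhesion receptor Gpr56 (66.8 and 4.64 FPKM, log2 ratio -3.59), the titin-associated protein Ankrd2 (84.4 and 6.48 FPKM, log2 ratio -3.51), Tnnc2, Dclk1 (163 and 17.8 FPKM, log2 ratio -3.12), Bex1 (257 and 29.1 FPKM, log2 ratio -3.10) and Cacna1s, the muscle voltage sensor (61.2 and 6.30 FPKM, log2 ratio -3.09). Loci without a gene symbol held 72.8% of the summed FPKM in male WT and 86.1% in male KO cells. Rescaling to TPM over all loci therefore moved the median log2 ratio of the genes from -0.02 to -0.70 and the share of higher calls from 60.5% to 9.12%. Over loci with a symbol the shift was to 0.15 and the share 71.6%.

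**Figure D2:**
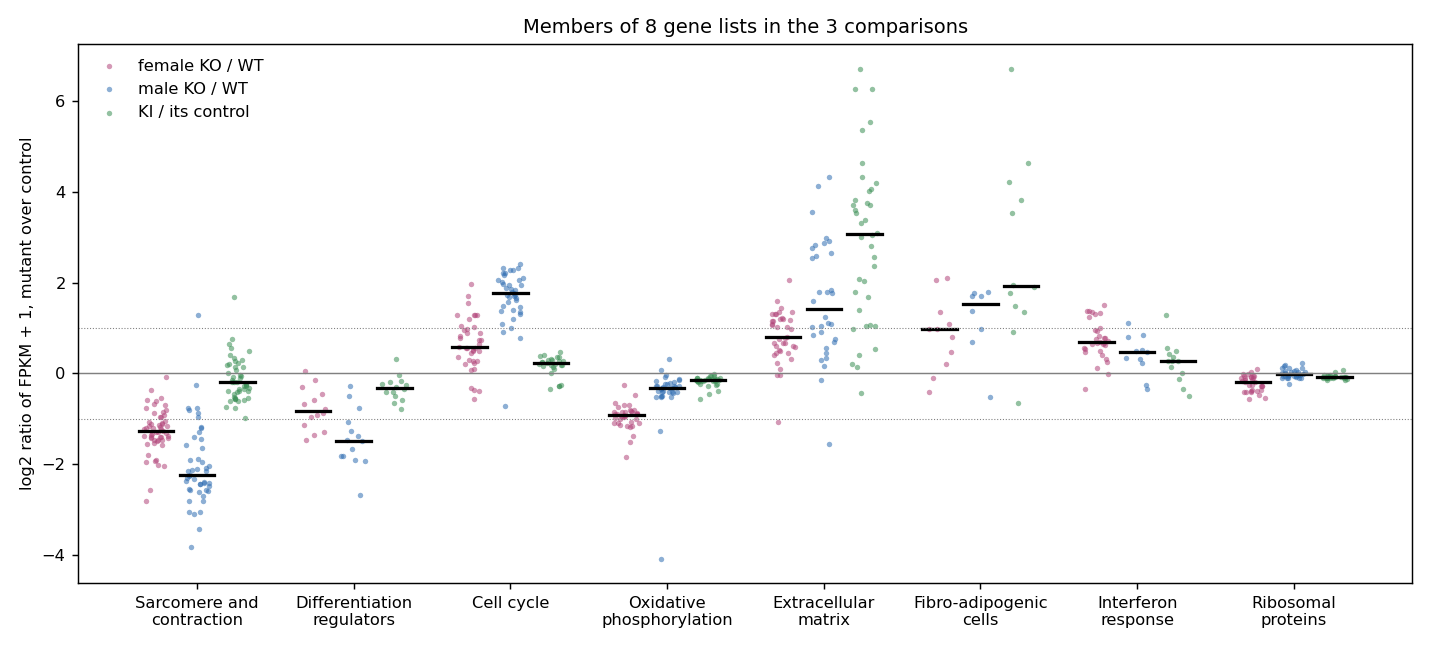
Log2 ratio of FPKM + 1, mutant over control, of each measured member (points) of 8 gene lists in the female KO, male KO and KI comparisons, with black bars at the list medians and dotted lines at 2-fold. Sarcomere medians were -1.26, -2.25 and -0.20 in the 3 comparisons, and matrix medians 0.80, 1.41 and 3.08.

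Taking each sex as 1 measurement of the KO effect, muscle genes fell and cell cycle and matrix genes rose within their lists. With limma on the 2 within-sex log2 ratios, 44 of 47 sarcomere and contraction genes fell at p adjusted over the list alone, as did 11 of 14 differentiation regulators. In turn 27 of 39 cell cycle genes and 23 of 32 matrix genes rose. Ckm changed by -3.32 ± 0.30 (mean log2 ratio of the 2 sexes ± moderated SE of limma), Pgam2 by -2.22 ± 0.22, Atp2a1 by -2.19 ± 0.21, Myog by -1.25 ± 0.31 and Mef2c by -1.82 ± 0.42. The moderated SE borrows spread from other genes and is not the spread between the 2 sexes. Mef2c, for instance, was -0.96 in females and -2.68 in males. Mki67 changed by 2.02 ± 0.25, Top2a by 1.98 ± 0.30 and fibronectin, Fn1, by 2.43 ± 0.52. Over the list alone, 4 of 8 chemokine genes, 4 of 8 fibro-adipogenic markers and 4 of 5 endothelial markers also rose, and 4 of 6 pericyte and smooth muscle markers fell. Genes under 1 FPKM in male WT, such as the endothelial Emcn, Cdh5 and Pecam1, entered this fit only through the male KO column. The filter fixed the direction of their male ratio, so the endothelial count is no support for a rise in both sexes. In females 0 of 9 endothelial genes reached 2-fold. The satellite cell list had 4 genes that rose and 6 that fell of 20, and the fusion list 2 and 6 of 16. Few genes passed in the other lists: 1 of 35 respiratory chain genes fell, 2 of 18 immediate early and stress genes, 1 of 14 p53 targets and 1 of 5 Wnt targets rose, 1 rose and 2 fell of 13 cell cycle exit genes, and 1 rose and 2 fell of 17 glycolysis genes. In the remaining lists it was 0. Over all 10482 genes, however, 0 passed an adjusted p of 0.05 in limma, with 1000 higher and 1079 lower at an unadjusted p under 0.05. The smallest adjusted p was 0.0505, for Gt(ROSA)26Sor at 4.15 ± 0.24.

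The KO effect rests here on 1 residual degree of freedom, and 30 of 100 simulated 2-fold changes and 100 of 100 simulated 8-fold changes were called at this size. Restricting the fit to genes with at least 5 FPKM in 1 column of each table brought 42 genes that rose and 88 that fell past the threshold, while without any filter the list-alone counts above all went to 0.

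Across genes, the female and male KO ratios correlated with a Pearson r of 0.534 (gene bootstrap interval 0.502 to 0.561) and a Spearman rho of 0.494 over 10482 genes, which are not independent replicates. The 2 comparisons have separate controls. Of 346 genes 2-fold higher in females and 962 in males 179 were shared, against 31.8 for independent lists, and of 474 and 661 lower genes 222 were shared, against 29.9. Opposite 2-fold ratios were found for 13 genes. The genes with the largest ratios of the same sign in both sexes were, on the lower side, Ckm (-2.81 and -3.83 in females and males), Tnnc2 (-2.56 and -3.44), Dhrs7c (-2.45 and -2.90), Apobec2 (-2.21 and -2.47), the calcium channel subunit Cacng6 (-2.13 and -2.26) and Atp2a1 (-2.05 and -2.34). Next came 2310015B20Rik (-2.07 and -2.04), muscle phosphoglycerate mutase Pgam2 (-2.02 and -2.43), Slc2a4 (in males 9.08 and 1.52 FPKM) and the muscle kinase Srpk3 (-1.97 and -2.26). On the higher side they were Gt(ROSA)26Sor (3.99 and 4.31), Snora68, which was listed at 0 in both WT libraries, Ptgs2 (2.72 and 2.33) and the protein C receptor Procr (2.04 and 3.03). Next came Mki67 (1.97 and 2.07), Plscr1 (1.89 and 2.07), the chromatin protein Hmga2 (in females 23.9 and 88.6 FPKM and in males 12.7 and 108), Cgnl1 (1.84 and 1.86), Fam111a (1.82 and 2.21) and Emp1 (1.74 and 3.03).

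**Figure D3:**
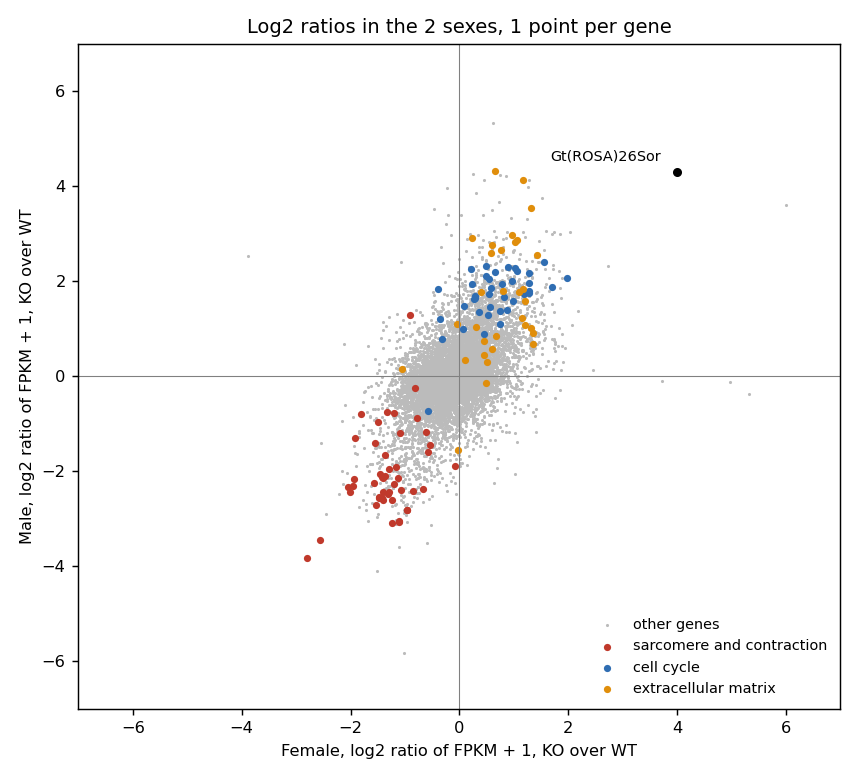
Log2 ratio of FPKM + 1, KO over WT, in females (horizontal axis) and males (vertical axis), 1 point per gene for 10481 genes, with 1 gene beyond the axes; sarcomere, cell cycle and matrix genes are coloured. Sarcomere genes lie mostly at the lower left, cell cycle and matrix genes mostly at the upper right, and Gt(ROSA)26Sor stands apart at 3.99 and 4.31.

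In the KI column, genes of matrix and connective tissue cells were higher than in its control, and the contractile genes lay near the control level. Of 38 matrix genes 32 were at least 2-fold higher and 0 lower, with a median log2 ratio of 3.08 (random range -0.12 to 0.02). The collagen genes Col1a1 (mm9 chromosome 11, 94797518 to 94814360) and Col1a2 were 0.515 and 158 FPKM, log2 ratio 6.72, and 0.943 and 149 FPKM, log2 ratio 6.27. Periostin, Postn, was 0.126 and 85.9 FPKM, log2 ratio 6.27, the collagen cross-linking enzyme Lox 1.85 and 132 FPKM, log2 ratio 5.55, and biglycan, Bgn, 8.22 and 379 FPKM, log2 ratio 5.36. Markers of fibro-adipogenic cells were at least 2-fold higher in 10 of 12 cases (median 1.93), including Dcn (0.171 and 28.3 FPKM) and Cd248 (0.205 and 21.5), while Tcf4 was lower at 48.8 and 30.5. All 8 immune genes kept were at least 2-fold higher (median 1.79). Lyz2, the macrophage lysozyme, was 0.282 and 31.0 FPKM and the complement gene C1qb 0.0180 and 3.91. Genes under 1 FPKM in Ctrl-KI, such as these and Dcn and Cd248, were kept only if they reached 1 FPKM in the KI column. For such genes the filter fixes the direction of the ratio, so these counts and medians partly follow from it. Of 10 pericyte and smooth muscle markers 4 were 2-fold higher, among them Pdgfrb (0.442 and 26.7 FPKM), with Mustn1 lowest at 157 and 89.9. The list median of 0.24 turned to -1.08 under TPM over all loci and to -0.26 at 5 FPKM or more. Eng was 2-fold higher of the 2 endothelial genes kept (2.12 and 7.64 FPKM).

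Sarcomere and contraction genes had a median of -0.20 in KI cells, just below their random range of -0.18 to -0.06, with 0 of 47 genes at least 2-fold lower and 1, Myh2, higher at 0.494 and 3.78 FPKM. The deposited intervals, which are narrower in this table, were apart for 7 lower and 4 higher genes of the 47. Ckm was 143 and 152 FPKM, Acta1 4333 and 3622, Myh3 569 and 803, Tmem8c 1070.2 and 1053, Myog 3201 and 2827 and Mef2c 113 and 99.6. The lowest members of this list were Ldb3 (283 and 142 FPKM, log2 ratio -0.99) and Myom3 (84.7 and 49.5 FPKM, log2 ratio -0.76). The myosin light chain gene Myl2, outside the list, was 30.4 and 9.61 FPKM, log2 ratio -1.56. The differentiation regulators had a median of -0.32, below -0.20 to 0.04, with 0 of 14 past 2-fold and Mef2a lowest at 234 and 135 FPKM. Intervals were apart for 3 of the 14, all lower. The satellite cell and myoblast list had a median of -0.24, below its random range of -0.16 to 0.04, while 3 of 21 genes were at least 2-fold higher, Cav1 (0.690 and 10.4 FPKM) the highest, and 0 lower. Pax7 was 3.33 and 3.30 FPKM, Myf5 5.91 and 8.76 and Myod1 906 and 619.9. Cell cycle genes were slightly higher, with 0 of 26 past 2-fold and a median of 0.22, above a random range of -0.08 to 0.16. This median was -0.34 under TPM over all loci, a setting that moved the median of all genes to -0.77. Chemokine genes were 2-fold higher in 5 of 9 cases (median 1.74), with Ptgs2 at 1.24 and 33.9 FPKM and Ccl7 at 0.0259 and 7.21. Cholesterol synthesis genes were lower in the KI column, with a median of -0.40 against a random range of -0.14 to 0.07. Idi1 was 25.04 and 13.0 FPKM and Cyp51 22.2 and 11.97, and 0 of 19 reached 2-fold.

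In all, 428 genes were at least 2-fold higher and 99 at least 2-fold lower in the KI column, with intervals apart for 411 and 89 of them. Small RNA genes took 7 of the 10 highest and 9 of the 10 lowest places. The genes with the lowest ratios apart from these were LOC100861570 (79.9 FPKM and listed at 0), the tubulin Tubb3 (23.8 and 2.82 FPKM, log2 ratio -2.70), securin, Pttg1 (17.1 and 2.45 FPKM, log2 ratio -2.39), Lynx1 (15.5 and 2.32 FPKM, log2 ratio -2.32) and the guidance factor Sema3d (47.6 and 9.07 FPKM, log2 ratio -2.27). Cdkn1c, further up, was 267 and 86.8 FPKM, log2 ratio -1.61. Apart from genes given above, the highest in the ranking without small RNA genes were Loxl2 (0.841 and 51.7 FPKM, log2 ratio 4.84), Igfbp7 (5.32 and 149 FPKM, log2 ratio 4.57), Inhba (0.560 and 32.0 FPKM, log2 ratio 4.40), the collagen gene Col6a3 (0.0733 and 20.5 FPKM, log2 ratio 4.32), Nid1 (1.08 and 39.7 FPKM, log2 ratio 4.29) and Cd200 (3.01 and 77.7 FPKM, log2 ratio 4.29). The 2 libraries of each group were combined by the authors, so it cannot be seen whether both KI libraries carried these genes. Loci without a symbol held 57.1% of the summed FPKM in the control and 77.6% in the KI column: under TPM over all loci the median log2 ratio moved from -0.04 to -0.77 and the share of higher calls from 81.2% to 10.4%.

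**Figure D4:**
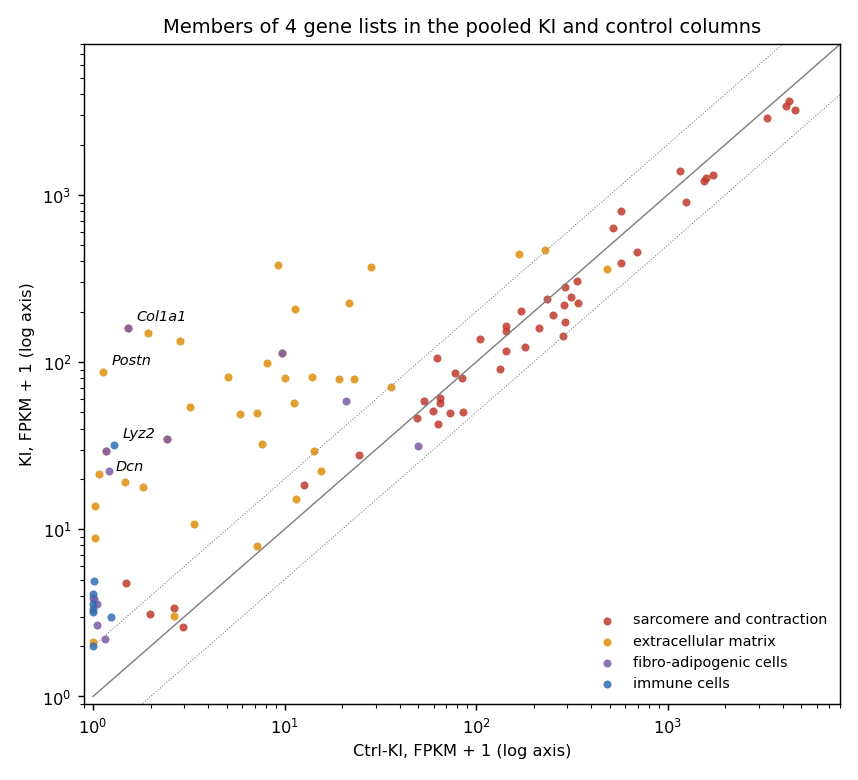
FPKM + 1 of sarcomere, matrix, fibro-adipogenic and immune genes in the pooled Ctrl-KI (horizontal) and KI (vertical) columns, both on log axes, with a solid line at equality and dotted lines at 2-fold in FPKM + 1. Col1a1 was 0.515 and 158 FPKM in Ctrl-KI and KI cells and Lyz2 0.282 and 31.0, while Acta1 was 4333 and 3622.

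Set beside the female KO, the KI ratios correlated across 10041 genes with a Pearson r of 0.337 (gene bootstrap interval 0.253 to 0.392) and a Spearman rho of 0.388. Of 312 genes 2-fold higher in female KO and 347 in KI cells 89 were shared, against 10.8 for independent lists, and of 449 and 52 lower genes 15 were shared, against 2.33. The matrix gene Fn1 was 1.31 and 3.39 on the log2 scale in female KO and KI cells and Dcn 2.06 and 4.64, and the inflammation gene Ptgs2 was 2.72 and 3.96. Contractile genes differed in size, with Ckm at -2.81 and 0.08 and Tnnc2 at -2.56 and -0.40. The difference between the comparisons was not tested, since neither has replicate values. Male KO and KI ratios, a pair added after the values were seen, correlated with a Pearson r of 0.464 (gene bootstrap interval 0.402 to 0.518) over 10245 genes. Of 861 and 304 higher genes 215 were shared, against 25.5 for independent lists, and of 664 and 71 lower genes 28, against 4.60.

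The other list medians are given here for female KO, male KO and KI cells in that order. Members of the UTX and MLL3/4 complexes had medians of -0.04, -0.25 and -0.05, and 2-fold ratios occurred in 1 case, Kdm6a in males. PRC2, the complex that writes H3 lysine 27 methylation, had 0.08, 0.02 and -0.07. Hox genes had -0.12, 0.42 and -0.07, with 5 of 17 2-fold higher in males, such as Hoxb9 (0.0896 and 3.40 FPKM), and 3 of 16 2-fold lower in KI cells, such as Hoxb8 (3.66 and 0.602). Notch pathway genes had 0.38, 0.22 and 0.24, with the Notch effector Rbpj at 88.0 and 192 FPKM in females and the ligand Jag1 at 2.11 and 17.4 in KI cells. The KI median was -0.51 under TPM over all loci, which moved the median of all genes to -0.70 in males and -0.77 in KI cells. Wnt targets had -0.11 in females and 0.66 in KI cells (-0.13 under TPM over all loci). The p53 targets had -0.05, 0.31 and 0.04, with Trp53inp1 at 49.3 and 138 FPKM in females, and the male and KI values turned to -0.47 and -0.76 under TPM over all loci. Immediate early and stress genes had 0.15, 0.00 and 0.39 (KI -0.33 under TPM over all loci). The unfolded protein response list had 0.31, -0.28 and 0.00, glycolysis 0.09, -0.05 and 0.23 (KI -0.60 under TPM over all loci), ribosomal proteins -0.19, -0.02 and -0.08 and cholesterol synthesis -0.23 and -0.18 in the KO comparisons. Interferon genes had 0.47 and 0.27 in male KO and KI cells, respiratory chain genes -0.14, fusion genes -0.02 and cell cycle exit genes -0.01 in KI cells. Pericyte and smooth muscle markers had -0.04 in females and -1.47 in males, where 4 of 7 were 2-fold lower, Acta2 (2000.3 and 724 FPKM) among them. Adipocyte markers had 0.08, 1.43 and 0.36, Schwann and glial markers 0.09, 0.01 and 0.14 and the X- and Y-linked genes 0.02, -0.27 and 0.13. The median of endothelial markers was 0.62 in females and 0.91 in KI cells, that of immune markers 0.60 in females and 1.51 in males, and 0 erythroid genes reached the 1 FPKM minimum.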

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

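All tests of explanations in this part were chosen after the results were seen. The KO ratio took opposite directions in the 2 sexes, by 2-fold or more each way and at 5 FPKM or more in both tables, for 9 genes. With 1 library per group these differences were not tested. The female and male tables also differ in their loci and their controls (given below), so the differences cannot be put down to sex. S100a4 was -1.07 in females and 2.41 in males, a difference of -3.48 on the log2 scale, S100a1 -1.40 in females and 1.14 in males, a difference of -2.54, Aldh3b1 -1.15 in females and 1.32 in males, a difference of -2.47, Bok -1.04 in females and 1.18 in males, a difference of -2.21 and Ldhb -1.30 in females and 1.25 in males, a difference of -2.55. In the other direction, Dok5 was 1.03 in females and -2.05 in males, a difference of 3.08, Gfod1 1.40 in females and -1.17 in males, a difference of 2.57 and Xirp2 1.06 in females and -1.38 in males, a difference of 2.44. For the microRNA gene Mir3960, listed at 0 in female WT cells, the difference of 12.05 has no fold behind it.

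Loci without a gene symbol, which the comparisons leave out, also differed between columns. In male KO cells 93 were at least 2-fold higher and 98 at least 2-fold lower, of 590 kept, and in KI cells 92 and 38, of 448. The most abundant in the male table was a 57-base locus at mm9 chromosome 18, 85867316 to 85867372, at 604313 FPKM in WT and 1653370 in KO cells.

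Sarcomere genes were lower in both KO libraries. Fewer myogenic cells would lower Pax7, Myf5, Myod1 and Cdh15 alike, yet all 8 of their values lay above the upper bound of the sarcomere median. Their median exceeded the sarcomere median by 0.61 in females and 1.69 in males on the log2 scale. By these markers, this argues against fewer myogenic cells as the whole cause. The result depends on the markers chosen. In the satellite cell and myoblast list, Des (-1.19 in females) and Ncam1 (-1.96 in males) did not lie above the bound (-1.16 and -1.95). The list medians were -0.04 and 0.00. The median log2 ratio of Pax7, Myf5, Myod1 and Cdh15 was still -0.65 in females and -0.57 in males. Myf5 (-0.63 in females and -0.61 in males), Myod1 (-0.87 and -0.52) and Cdh15 (-0.67 and -0.99) were lower in both sexes. Pax7 was higher in both (0.30 and 1.34). A partial loss of myogenic cells therefore stays open. After correction for transcript length and GC content the sarcomere medians were -1.23 and -2.30, so that trend was not the whole cause either. The values also go with less advanced differentiation, for which cell cycle genes should be higher and differentiation regulators lower. Both held in the 2 sexes (the smaller of the 2 cell cycle medians was 0.57). These medians were known when the explanation was chosen, so they are no independent support for it. Less advanced differentiation stays a hypothesis, since the share of cells at each stage was not measured. Other cells, whose matrix and endothelial markers were higher, may add to the change although the reporter sort should remove them.

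Matrix, fibroblast and immune genes were higher in the KI column. A bias by transcript length or GC content left a matrix median of 2.99 after correction and was not the whole cause. Fibroblasts and immune cells in the KI libraries would raise genes that myogenic cells do not use. The immune list, which has 8 of its 18 genes detected, had a median of 1.79. Genes under 1 FPKM in Ctrl-KI were kept only through the KI column, so this median partly follows from the filter and is weak support. The most abundant immune gene, Lyz2, reached 31.0 FPKM and the fibroblast gene Dcn 28.3, although cells were sorted for a reporter that should exclude both types. Matrix genes switched on in the KI myogenic cells cannot be told apart from this, since the matrix list without the genes it shares with the fibroblast list still had a median of 2.90 and both kinds of cell use these genes. The pooled columns also hide whether 1 of the 2 KI libraries carries the signal.

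Gt(ROSA)26Sor was higher in both KO libraries and not in the KI column (-0.68). A change of the whole region would raise its neighbours, but the highest ratio of any gene within 500 kb was 1.75 in males and 0.77 in females, and the neighbours' medians were -0.25 in females and -0.23 in males. Reads shared with the overlapping genes Thumpd3 and Setd5 would have to be lost there. Weighted by transcript length, these genes together gained 93.5 FPKM kb in females, against a gain of 70.5 for Gt(ROSA)26Sor. The sum covers opposite changes, with Setd5 at 96.8 and 113 FPKM and Thumpd3 at 14.2 and 9.59. In females this argues against reads lost from Setd5 but leaves a part from Thumpd3 open. In males the sum changed by -107 against 64.9, so there the explanation stays open. The labels give WT and KO mice the same reporter genotype, which speaks against different Rosa26 alleles, but they do not give the number of reporter copies, so this stays open. No test here bears on a direct effect of UTX.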

How the results depend on the processing

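The settings named as added in the methods were chosen after seeing the data; the cause of the changes below was not tested unless given. No paired analysis was possible because, within the KI comparison, the pooled columns carry no replicate number, and leaving out a KI replicate could not be run for the same reason. The joint KO fit pairs KO and WT within each sex. Over all alternatives, 726 list medians stayed within their bootstrap interval, 105 moved and, of those outside their random range, 9 turned sign. Of named genes' ratios 1550 stayed within the range their deposited bounds allow and 119 moved, and 0 of those past 2-fold turned. Some settings cannot change these values. Adding loci without a symbol or leaving out small RNA genes alters no list member, and filters and status leave the ratio of a kept named gene as it was. The counts that stayed are therefore partly fixed by construction. Unknown depth and wide deposited intervals limit the single ratios: with non-overlapping intervals required, the genes at least 2-fold higher and lower were 81 and 29 (female) and 69 and 30 (male), against 554 and 543, and 1132 and 740.

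With a pseudocount of 0.1 FPKM, 938 genes were 2-fold higher in females and 168 lower in KI cells (99 at 1 FPKM); with 5 FPKM, which shrinks low genes by construction, the higher and lower counts were 196 and 246 (female), 443 and 475 (male) and 177 and 47 (KI, against 428 and 99). Requiring 5 FPKM left 262 genes higher in KI cells. TPM over all loci gave 1197 genes higher in females, as did TPM over loci with a symbol, since that table has no other loci. In the other tables it gave 253 higher and 2521 lower (male) and 196 higher and 1683 lower (KI), where loci without a symbol hold a larger share of the mutant columns. TPM over loci with a symbol gave 1799 genes higher in males and 679 in KI cells. Under TPM over all loci, list medians turned to -0.47 for male p53 targets and, in KI cells, to -0.51 (Notch), -0.13 (Wnt targets), -0.34 (cell cycle), -0.76 (p53 targets), -0.33 (immediate early), -0.60 (glycolysis) and -1.08 (pericyte and smooth muscle), the last also to -0.26 at 5 FPKM. This TPM setting moved the median of all genes to -0.70 (male) and -0.77 (KI), and the random range was not recomputed for it. Except for pericyte and smooth muscle markers, these list medians lay at or above the median of all genes. Their change of sign is thus no reversal against the other genes.

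In the joint limma fit, 1 gene rose at an adjusted p under 0.05 with a pseudocount of 0.1 FPKM and 1 with small RNA genes left out. At 5 FPKM 42 rose and 88 fell, with 623 higher at an unadjusted p under 0.05 (1000 before), among 7732 genes. Adjusted over the list alone, sarcomere genes that fell went from 44 of 47 to 24 of 42 with the KI ratio as an additional value, and cell cycle genes that rose from 27 to 0 of 26. Without the filter 0 sarcomere, 0 cell cycle and 0 matrix genes passed. Between the sexes, r went from 0.534 to 0.430 without the filter, and 349 genes were higher in both at a pseudocount of 0.1 FPKM (179 at 1). Between female KO and KI, r went from 0.337 to 0.2503 without the filter, and 156 genes were higher and 24 lower in both at 0.1 FPKM (89 and 15 at 1). For male KO and KI these were 0.464 to 0.359, and 329 and 53 (215 and 28 at 1).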

Other observations

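The 2 female controls differed more from each other than Ctrl-KI did from male WT. Over 11552 genes common to the tables, log2(FPKM + 1) correlated across genes with an r of 0.883 between female WT and Ctrl-KI, 0.874 between female WT and male WT, and 0.989 between male WT and Ctrl-KI. At least 8-fold differences in FPKM + 1 separated female WT from Ctrl-KI in 186 genes and male WT from Ctrl-KI in 9. Female WT was at least 8-fold above both other controls in 149 genes and below both in 14. Carbonic anhydrase 9, Car9, was 234 FPKM in female WT, 0.343 in male WT and 1.10 in Ctrl-KI cells. In the same order, the angiogenic factor Vegfa was 1512, 87.1 and 72.0 FPKM, heme oxygenase Hmox1 949, 44.5 and 34.2, the chemokine Ccl2 101, 0.208 and 0.140, Nos2 36.6, 0 and 0.00158, Saa3 109.6, 0.436 and 0.0704, Col1a1 127, 1.08 and 0.515 and Postn 95.3, 0.274 and 0.126. Some myogenic genes were lower in female WT and others not: Myod1 was 189.9, 1005 and 906 FPKM, Cdh15 74.0, 433 and 430.3 and Myog 1305, 3424 and 3201, against 12.5, 5.38 and 5.91 for Myf5 and 147, 110.0 and 143 for Ckm. The ribosomal gene Rpl4 was 782, 819.9 and 763. The tables were estimated separately and each control is 1 column, so these levels were not tested. The female KO column shared these high levels, with Car9 at 224 FPKM, Ccl2 at 148 and Nos2 at 88.8. The female pair, not WT alone, thus stood apart, and the joint KO fit uses this pair beside the male pair. A scaling difference between tables would move all genes alike, so the 149 genes above and 14 below argue against scaling as the whole cause. The female KO table also has 0 loci without a symbol, against 5680 and 5971 in the male and KI tables. Effects of its gene models on single genes therefore cannot be told apart from library differences here.

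Of 13 imprinted genes kept in all 3 tables, a group chosen after values of some were seen and not tested, 3 were lower in all 3 mutant columns (Igf2, Cdkn1c and Grb10), 3 were higher in all (Mest, Ndn and Nnat) and 7 differed in both directions. On the log2 scale, in female KO, male KO and KI cells, Grb10 was -0.53, -1.07 and -0.63. The growth factor Igf2 was 738 and 346 FPKM in female WT and KO cells, 1869.8 and 659 in male WT and KO cells and 2236 and 1315 in Ctrl-KI and KI cells. The cell cycle inhibitor Cdkn1c, given above for both KO comparisons, had a log2 ratio of -2.17 in male KO and -1.61 in KI cells. In the same order Mest was 0.58, 1.58 and 0.50, Ndn 0.20, 0.31 and 0.81, Plagl1 0.66, 2.36 and -0.59 and Peg3 -0.94, 0.37 and -0.44. H19, the noncoding neighbour of Igf2, was 3094 FPKM in female WT and 1356 in female KO cells. In male KO cells it was 3909.7 FPKM, and it is listed at 0 without an estimate in male WT, Ctrl-KI and KI cells. The metalloproteinases Mmp3, Mmp10 and Mmp13, among the highest genes in female KO cells, were at 0.0743, 0.520 and 0.287 FPKM in male KO cells.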
